A study of Homo sapiens with 16 samples.

How the data were processed

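RNA sequencing of messenger RNA was analysed for 16 libraries from 2 human triple-negative breast cancer cell lines, MDA-MB-231 and SUM159 (SUM159PT in the sample titles). Each line was treated for 48 h with the solvent DMSO or with 8 uM of YES1i (CH6953755), an inhibitor of the Src family kinase YES1, with 4 libraries per group. Per the labels' protocols, cells were plated the day before treatment, in RPMI for MDA-MB-231 and in Ham's F12 for SUM159, so that line and medium cannot be separated. Messenger RNA was selected with poly-T beads and copied with random hexamers, per the labels. The labels leave open whether the library kit kept the strand. The series text describes the 4 libraries of a group as technical replicates, so the p-values here measure only the spread between these libraries, which may be smaller than that between independent cultures.

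The authors deposited one table of read counts per gene, with a column for each library. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build hg38, with no role or order. The annotation release and the counting rules for strand, overlapping genes and multi-mapped reads are not given in the sources used here. Values of near-identical copies, such as tubulins and ribosomal proteins with their pseudogenes, and of overlapping genes are therefore uncertain. Of the 122 named genes, 61 overlapped a gene on the opposite strand, and 23 overlapped a gene whose total count was at least 10% of their own. Coordinates, gene names and biotypes are those of the deposited table.

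Total counts ran from 15876171 to 36261542 per library. A count of 0 allows, at 3 counts, a level of up to 0.0827 to 0.189 CPM depending on the library. This limit covers counting error only. Of 58735 genes in the table, 17647 passed edgeR's filterByExpr with the 4 groups and were tested, 13799 of them protein-coding. The counts were used as deposited in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling and the robust quasi-likelihood F test in one fit of all 16 libraries with a mean per group. The contrasts were YES1i minus DMSO in each line and the difference between those changes, MDA-MB-231 minus SUM159. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, and a gene was called at an adjusted p under 0.05. CPM values are scaled with the TMM factors and given as mean ± SD with n = 4. Standard errors of log2 fold changes were derived from the F statistic.

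Before the data were examined, 29 gene lists were fixed for cell division, DNA replication and repair, Src, YAP/TAZ, SRF and ERK signalling, stress, metabolism, drug efflux and other cell types. Of these, 28 had at least 3 tested genes and were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a contrast. Each test was repeated with a correlation estimated from the data, which gave larger p-values for every called list. Counts of changed members are over all genes tested, and counts adjusted over the list alone are added wherever they differ. The remaining list, markers of leukocytes, had 2 tested genes and is given as values. The named genes were also fixed by rule. They were YES1 and the tested Src family kinases, and in each line the 5 protein-coding genes with the largest rise and the 5 with the largest fall, among those called, at 5 CPM or more on average and with no overlap between groups. They included, of the called genes at 5 CPM or more in a line, the 3 most changed members of each list called there and the most changed member of every other list. The last were the 4 protein-coding genes with the largest called differences between lines in each direction, at 5 CPM or more in each line, and FOXM1, AURKA, AURKB, PLK1, CCNB1, CDK1, BUB1, CDKN1A, CYR61, CTGF, TUBB3 and ABCB1. Genes outside the rule are named as chosen after their values were seen.

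The steps were tested on simulated counts drawn from the means and spread of the real genes, with 17358 genes tested and 50 or 70 genes changed at each known fold in each line. For MDA-MB-231, 58% of genes changed 1.25-fold, 98.6% of those changed 1.5-fold and 100% of those changed 2-fold were recovered, with 2.46% false calls. For SUM159 the shares were 52%, 96% and 100%, with 7.45% false calls. For the difference between lines they were 25%, 73.3% and 100%, with 2.80% false calls. Changes were placed only in genes at 5 CPM or more on average in each line. Far fewer genes changed than in the data, where 48.9% were called in MDA-MB-231 and 51.6% in SUM159. One spread per gene served both lines. Replicate pairs reached a chi-square over degrees of freedom of 24.4 in SUM159 and 7.93 in MDA-MB-231. These shares may therefore not hold for the real data.

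The alternatives, fixed at the same time, were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean count of 10, a fit per line, a replicate block, an adjusted p under 0.01, a log2 fold change of at least 1, edgeR's glmTreat against 1.2-fold, fry, and leaving out each library in turn. No pair of replicates was within sampling noise (chi-square over degrees of freedom of at least 2.38). All 16 libraries were counted, though this test cannot show that they came from independent cultures. Levels of sex-linked genes are not reported.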

Results

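Gene expression was measured by sequencing of poly(A) RNA in MDA-MB-231 and SUM159 (SUM159PT in the sample titles), both established human lines of triple-negative breast cancer, a form that lacks the oestrogen and progesterone receptors and HER2 amplification. Cells of each line received DMSO, the solvent control, or 8 uM of YES1i (CH6953755), a small-molecule inhibitor of the Src family tyrosine kinase YES1, and were collected after 48 h. Each of the 4 groups held 4 libraries, 16 in all. Total counts per library ran from 15876171 to 36261542, and 17647 genes were tested. The series concerns YES1, faithful mitosis and taxane response. The comparisons ask which transcripts differ with the inhibitor in each line, and whether the lines differ in that response. The first principal component of log2 CPM held 86.6% of the variance, the second 5.46% and the third 2.11%. The first separated the lines, and the second separated YES1i from DMSO in the same direction in both lines. On the third the treatments lay in opposite order in the lines.

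Libraries also differed with treatment in their makeup. The share of counts from mitochondrial rRNA was 0.644% with DMSO and 1.33% with YES1i in MDA-MB-231, and 0.731% and 1.34% in SUM159. The two-sided exact permutation p was 0.0286 in each line (n = 4), the smallest that 70 regroupings allow. The share from mitochondrial mRNA was 1.08 times that with DMSO in MDA-MB-231 (exact p = 0.286) and 0.916 times in SUM159 (exact p = 0.543). The 20 genes with most counts held 7.94% of counts with DMSO and 9.58% with YES1i in MDA-MB-231 (exact p = 0.0286). In SUM159 they held 10.01% and 12.6% (exact p = 0.0286). Protein-coding genes held 97.8% of counts with DMSO and 97.0% with YES1i in MDA-MB-231, and 97.3% and 96.1% in SUM159 (exact p = 0.0286 in each). In SUM159 the share of lincRNA was 1.44 times and that of antisense RNA 1.24 times that with DMSO (exact p = 0.0286 for each). In MDA-MB-231 these ratios were 1.17 (exact p = 0.114) and 1.03 (exact p = 0.571). The TMM factor had a mean of 1.04 with DMSO and 1.01 with YES1i in MDA-MB-231 (exact p = 0.0286).

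In MDA-MB-231, genes of cell division, DNA replication and DNA repair fell with YES1i, while genes of cholesterol synthesis and of lysosomes rose. All 24 genes of cholesterol synthesis were higher, with a median log2 fold change of 1.73, and 43 (44 adjusted over the list alone) of 44 genes of G2/M and mitosis were lower, with a median of -1.38. HMGCS1, which makes HMG-CoA for the sterol pathway, rose from 39.2 ± 2.24 to 329 ± 18.1 CPM (SD, n = 4). CCNB1, the cyclin that drives entry into mitosis, fell from 299 ± 2.95 to 124 ± 11.7 CPM. Of 28 lists camera called 12, of which 9 hold with an estimated correlation. In all, 4737 genes were higher and 3892 lower with YES1i (edgeR, adjusted p under 0.05), of which 1114 and 670 differed at least 2-fold. Higher genes made up 54.9% of these calls, but 47.9% in a fit of MDA-MB-231 alone (4503 higher and 4906 lower).

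The gene of the drug's target, YES1 (ENSG00000176105, chromosome 18, 721588 to 812546 on hg38), went from 94.3 ± 3.92 to 93.3 ± 5.32 CPM in MDA-MB-231. Its log2 fold change was -0.02 (SE 0.06), with an edgeR adjusted p = 0.86. Of the other Src family kinases, SRC rose by 0.23 (SE 0.07) on the log2 scale and FRK, at low levels, from 0.779 ± 0.115 to 2.09 ± 0.114 CPM. LYN rose by 0.18 (SE 0.07) with an edgeR adjusted p = 0.0304, a call that ended with no low-count filter (adjusted p = 0.165) and in a fit of MDA-MB-231 alone (0.0954). It also ended without DMSO replicate 2 (adjusted p = 0.112), DMSO replicate 4 (0.0688), YES1i replicate 1 (0.0615) or YES1i replicate 4 (0.168). FYN had a log2 fold change of -0.11 (edgeR adjusted p = 0.15), called in a fit of MDA-MB-231 alone (-0.16, adjusted p = 0.015). BLK, which overlaps another gene, had 0.59 (adjusted p = 0.488). The Src family list as a whole had a median of 0.21 (camera adjusted p = 0.698). Src and focal adhesion partners had 8 members higher and 12 lower of 25, with a median of -0.08 (camera adjusted p = 0.452). Among them CAV1, the main protein of caveolae, fell from 916 ± 12.3 to 444 ± 26.8 CPM.

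Genes of mitosis fell together (camera adjusted p = 4.6e-81 for G2/M, and 1.2e-04 with an estimated correlation). MKI67, a marker of cycling cells, fell from 887 ± 29.3 to 288 ± 13.4 CPM. CDC20, an activator of the anaphase-promoting complex, had a log2 fold change of -1.61 (SE 0.06) and the spindle-associated hyaluronan receptor HMMR of -1.60 (SE 0.14). The transcription factor FOXM1, which drives many mitotic genes, had a log2 fold change of -1.29 (SE 0.06). The mitotic kinases AURKA, PLK1 and CDK1 had -1.33 (SE 0.06), -1.48 (SE 0.06) and -1.31 (SE 0.09). Of 40 genes of the kinetochore and spindle checkpoint, which holds anaphase until chromosomes are attached, 37 fell, with a median of -1.36 (camera adjusted p = 2.31e-47). They included SKA3, which links kinetochores to microtubules, at -1.77 (SE 0.09), CENPK at -1.72 (SE 0.09), the Ndc80 complex member SPC25 at -1.62 (SE 0.09). The checkpoint kinase BUB1 was at -1.50 (SE 0.06) and AURKB at -1.42 (SE 0.07). Of 22 genes of the centrosome and spindle pole 17 fell and 3 rose (median -0.57, camera adjusted p = 7.49e-08). PLK4, the kinase that starts centriole duplication, and its partners CEP152 and STIL had log2 fold changes of -1.39 (SE 0.07), -1.19 (SE 0.13) and -1.02 (SE 0.07).

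Genes of DNA replication and repair were lower as well. All 42 genes of DNA replication and G1/S fell, with a median of -1.23 (camera adjusted p = 2.13e-59, and 1.83e-04 with an estimated correlation). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, fell from 117 ± 2.23 to 30.6 ± 2.12 CPM. The thymidylate synthase gene TYMS fell from 76.1 ± 1.40 to 22.9 ± 4.14 CPM and UHRF1, which helps to copy DNA methylation, from 223 ± 7.10 to 67.8 ± 9.45 CPM. Of 23 repair genes 20 (21 adjusted over the list alone) fell (median -1.23, camera adjusted p = 5.17e-24). They included the homologous recombination genes RAD54L at -1.70 (SE 0.10) and RAD51AP1 at -1.56 (SE 0.08) and the nuclease gene EXO1 at -1.55 (SE 0.09).

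The rise in sterol genes spanned the pathway (camera adjusted p = 1.3e-84, and 4.01e-05 with an estimated correlation). MSMO1, a demethylase of sterol synthesis, rose from 68.5 ± 3.76 to 545 ± 36.5 CPM, and the sterol reductase gene TM7SF2 from 14.7 ± 0.475 to 72.9 ± 3.94 CPM. INSIG1, which holds the SREBP activators in the endoplasmic reticulum, rose from 109 ± 5.29 to 366 ± 8.75 CPM. ABCA1, which exports cholesterol (ENSG00000165029, chromosome 9, 104781002 to 104928237), fell from 79.9 ± 4.33 to 9.13 ± 1.26 CPM. That was the largest fall among called protein-coding genes at 5 CPM or more with no overlap between groups. LIPG, the endothelial lipase, rose by 2.12 (SE 0.07). Of 27 genes of autophagy and the lysosome 25 rose and 1 fell (median 0.81, camera adjusted p = 2.44e-25). The autophagy receptor SQSTM1 rose from 195 ± 11.3 to 1038 ± 52.6 CPM, the lysosomal sialidase NEU1 by 1.85 (SE 0.06) and CTSA, which protects it, by 1.41 (SE 0.05) on the log2 scale. ATP6V0D2, a subunit of the proton pump of acidic compartments, had the largest rise of such genes, from 0.306 ± 0.0461 to 11.2 ± 0.366 CPM.

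Other large rises were KCP, a secreted regulator of BMP signalling, at 4.49 (SE 0.22), NUPR1, a stress-induced chromatin protein, at 3.96 (SE 0.16), the stress cytokine GDF15 at 3.53 (SE 0.11) and C6orf223 at 3.43 (SE 0.17). Other large falls were MARCH4, a membrane ubiquitin ligase, at -2.57 (SE 0.13), the cytokine IL11 at -2.54 (SE 0.11) and the transcription factor ZNF488 at -2.02 (SE 0.10). Targets of the aryl hydrocarbon receptor, a sensor of many small aromatic compounds, rose (6 of 7, 1 lower, median 1.16, camera adjusted p = 2.68e-07). The cytochrome P450 gene CYP1A1 was at 2.36 (SE 0.14), CYP1B1 at 2.01 (SE 0.07) and TIPARP, a repressor of the receptor, at 1.16 (SE 0.06). Of 22 targets of YAP/TAZ and TEAD 17 fell and 4 rose (median -0.55, camera adjusted p = 2.34e-06). The matricellular gene CTGF fell from 231 ± 5.99 to 112 ± 3.69 CPM and CYR61 from 815 ± 24.3 to 497 ± 46.4 CPM. The kinase gene NUAK2 was at -0.95 (SE 0.14) and the receptor kinase gene AXL at -0.93 (SE 0.05).

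Calls of 3 lists in MDA-MB-231 did not hold with an estimated correlation. Tubulins and microtubule regulators, the proteins taxanes act on among them, had 12 members lower and 5 higher of 20 (median -0.30, camera adjusted p = 0.0179; adjusted p = 0.236 with an estimated correlation). TUBA1A rose from 109.9 ± 5.13 to 276 ± 10.5 CPM, while TUBA1B fell from 662 ± 34 to 325 ± 17.1 CPM and the microtubule destabiliser STMN1 from 506 ± 17.2 to 237 ± 18.6 CPM. Heat shock genes had 9 of 14 lower and 2 higher (median -0.32, camera adjusted p = 0.0179; adjusted p = 0.183 with an estimated correlation). The chaperone gene HSPA4L was at -1.14 (SE 0.07), HSPD1 at -0.59 (SE 0.05) and HSPE1 at -0.53 (SE 0.09). ERK pathway output had 11 of 22 higher and 5 lower (median 0.17, camera adjusted p = 0.0483; adjusted p = 0.461 with an estimated correlation). The ERK phosphatase gene DUSP5 rose from 70.4 ± 2.36 to 145 ± 7.37 CPM, with the ETS factor ETV1 at 1.01 (SE 0.06) and the feedback inhibitor SPRY2 at 0.72 (SE 0.06). That call also ended with RLE scaling (adjusted p = 0.0504), a mean count filter (0.0539), a fit of MDA-MB-231 alone (0.0905) and the replicate number as a block (0.0573). It ended without MDA-MB-231 DMSO replicate 1 (0.0581), 2 (0.0515) or 3 (0.0591) and YES1i replicate 3 (0.0607) or 4 (0.0541). It also ended without SUM159 DMSO replicate 2 (0.0509), 3 (0.0529) or 4 (0.0551) and YES1i replicate 1 (0.0514).

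Lists with no camera call in MDA-MB-231 still held single genes that changed. Among p53 targets 10 (11 adjusted over the list alone) rose and 7 fell of 26 (median 0.16, adjusted p = 0.269), and the cell cycle inhibitor CDKN1A rose from 98.6 ± 5.89 to 185 ± 12 CPM. Drug efflux transporters had 3 higher and 1 lower of 8 (median 0.13, adjusted p = 0.115), with ABCC3 at 1.75 (SE 0.06). ABCB1, the main taxane exporter, had 0 counts in all 8 MDA-MB-231 libraries, which allows up to 0.186 CPM in YES1i replicate 2, the shallowest of them. Integrated stress and unfolded protein response genes had 13 higher and 8 (9 adjusted over the list alone) lower of 26 (median 0.29, adjusted p = 0.344), with the pseudokinase TRIB3 at 1.13 (SE 0.13). Interferon response genes had 11 (12 adjusted over the list alone) higher and 5 lower of 29 (median 0.13, adjusted p = 0.29), with IFI27 at 1.31 (SE 0.22). Extracellular matrix and mesenchymal genes had 8 (9 adjusted over the list alone) higher and 11 lower of 34 (median -0.07, adjusted p = 0.893), with a mean of 0.07 and a test direction of down. Fibronectin, FN1, rose from 615 ± 28 to 2626 ± 130.0 CPM.

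Further lists in MDA-MB-231 had no camera call. NF-kB and inflammatory cytokines (median 0.09, adjusted p = 0.871) included IL11. Hypoxia and glycolysis genes (median -0.19, adjusted p = 0.824) included the aldolase gene ALDOC at 2.01 (SE 0.08). SRF/MRTF cytoskeletal targets (median -0.13, adjusted p = 0.657) included FILIP1L at 0.74 (SE 0.16). Epithelial genes (median 0.08, adjusted p = 0.421) included the mucin MUC1 at 1.03 (SE 0.08). Apoptosis regulators (median 0.03, adjusted p = 0.824) included the BCL2 family member BMF, which promotes apoptosis, up from 6.60 ± 1.09 to 39.3 ± 1.62 CPM. Mitochondrially encoded mRNAs (median 0.00, adjusted p = 0.893, test direction down) included MT-CO1 at 0.61 (SE 0.14). Cytosolic ribosomal proteins (median -0.01, adjusted p = 0.769) included RPL35 at -0.37 (SE 0.07), and replication-dependent histones (median -0.09, adjusted p = 0.921) HIST1H2BD at 0.85 (SE 0.11). Of markers of other cell types, those of endothelium and fibroblasts (median 0.60, adjusted p = 0.657) included PECAM1, which rose from 3.20 ± 1.07 to 8.67 ± 0.651 CPM. The leukocyte markers CD14 and CSF1R had log2 fold changes of -0.36 (edgeR adjusted p = 0.219) and 0.41 (edgeR adjusted p = 0.0136). TUBB3, the neuronal beta-tubulin, had a log2 fold change of -0.29 (SE 0.37) (edgeR adjusted p = 0.556). Values of KCP, C6orf223, SPC25, TYMS, RAD54L, FILIP1L, TUBA1A, HSPE1, TM7SF2, SQSTM1, ALDOC, FOXM1, BLK and ABCB1 are uncertain, since each overlaps a gene with a count of at least 10% of its own, and neither the strand setting nor the counting rule for overlapping genes is given.

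In SUM159, genes of mitosis, replication and repair fell with YES1i, and so did all 24 genes of cholesterol synthesis, with a median log2 fold change of -1.10. Inflammatory cytokines of the NF-kB list fell too, with 19 of 23 lower and 0 higher. CXCL8, a chemokine that attracts neutrophils (ENSG00000169429, chromosome 4, 73740506 to 73743716), fell from 222 ± 25 to 4.41 ± 0.548 CPM (SD, n = 4). HMGCS1 fell from 338 ± 27.9 to 39.9 ± 1.71 CPM. Of 28 lists camera called 16, of which 13 hold with an estimated correlation. In all, 4431 genes were higher and 4674 lower (edgeR, adjusted p under 0.05), of which 1186 and 564 differed at least 2-fold. Higher genes made up 48.7% of these calls, but 55.0% with RLE scaling (5052 higher and 4137 lower) or DESeq2 (5105 and 4185). With no low-count filter they made up 50.2% (4495 and 4458), and with upper quartile scaling 63.4% (5985 and 3454), which moved the median log2 fold change of all genes from 0.02 to 0.14.

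YES1 transcripts went from 103 ± 3.61 to 88.9 ± 7.58 CPM in SUM159. Their log2 fold change was -0.21 (SE 0.06) (edgeR adjusted p = 0.00392), and -0.09 with upper quartile scaling (adjusted p = 0.206). The difference between lines was not called for YES1. Relatives of YES1 moved in both directions: LYN fell by 0.41 on the log2 scale and FYN rose by 0.24 (SE 0.06). FRK and BLK, both at low levels, rose by 0.84 (SE 0.25) and 0.98 (SE 0.27). SRC had a log2 fold change of 0.07 (edgeR adjusted p = 0.399), called with upper quartile scaling (0.19, adjusted p = 0.0134). For SRC the difference between lines was 0.16 (SE 0.09) (edgeR adjusted p = 0.193). The Src family list had 3 members higher and 2 lower of 6 (median 0.15, camera adjusted p = 0.829). Src and focal adhesion partners had 7 higher and 9 lower of 25 (median -0.04, camera adjusted p = 0.885). The integrin gene ITGB4 rose from 180.1 ± 13.4 to 341 ± 29.1 CPM.

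All 44 genes of G2/M and mitosis fell in SUM159 (median -1.07, camera adjusted p = 3.14e-55, and 8.64e-04 with an estimated correlation). MYBL2, a transcription factor of the cell cycle, fell from 162 ± 2.41 to 53.8 ± 2.89 CPM. CDC20 fell from 234 ± 3.21 to 88 ± 6.73 CPM and CCNB1 from 262 ± 5.97 to 103 ± 8.41 CPM. FOXM1 had a log2 fold change of -1.03 (SE 0.06), AURKA of -1.33 (SE 0.07), PLK1 of -1.08 (SE 0.06) and CDK1 of -1.01 (SE 0.09). Of 40 genes of the kinetochore and spindle checkpoint 38 (40 adjusted over the list alone) fell (median -1.01, camera adjusted p = 8.62e-33). SPC25 was at -1.60 (SE 0.09), CENPI at -1.56 (SE 0.09), ZWINT at -1.53 (SE 0.07), BUB1 at -1.26 (SE 0.06) and AURKB at -1.33 (SE 0.07). Of 22 centrosome and spindle pole genes 18 (19 adjusted over the list alone) fell and 1 rose (median -0.42, camera adjusted p = 5.62e-06). PLK4 was at -1.21 (SE 0.08), the gamma-tubulin gene TUBG1 at -1.19 (SE 0.07) and STIL at -1.03 (SE 0.08). All 42 genes of DNA replication and G1/S fell (median -1.37, camera adjusted p = 1.22e-69, and 7.53e-04 with an estimated correlation). CLSPN, an adaptor of the replication checkpoint, fell from 29.4 ± 4.34 to 7.48 ± 1.09 CPM, RRM2 from 125 ± 12 to 32.4 ± 5.82 CPM and UHRF1 from 119 ± 14.2 to 32.6 ± 2.42 CPM. Of 23 repair genes 22 fell and 1 rose (median -1.10, camera adjusted p = 6.12e-21). EXO1 was at -1.69 (SE 0.09), the helicase gene BLM at -1.59 (SE 0.11) and RAD54L at -1.46 (SE 0.10).

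Sterol genes had a camera adjusted p = 1.07e-47, and 4.65e-04 with an estimated correlation. They included ACAT2, a thiolase at the start of the pathway, which fell from 69.8 ± 3.62 to 13.8 ± 0.627 CPM. INSIG1 fell from 232 ± 5.33 to 54 ± 3.97 CPM. LIPG fell from 14.2 ± 0.954 to 1.47 ± 0.418 CPM, and ABCA1 rose from 4.96 ± 0.352 to 16.9 ± 1.67 CPM. Among NF-kB targets and cytokines (median -0.97, camera adjusted p = 1.68e-15) the chemokine genes CXCL2 and CXCL3 had log2 fold changes of -2.72 (SE 0.11) and -1.96 (SE 0.17), against -5.64 for CXCL8. ERK pathway output had 13 of 22 lower and 1 higher (median -0.36, camera adjusted p = 2.66e-06, and 0.0454 with an estimated correlation). The immediate early gene EGR1 fell from 16.5 ± 3.21 to 2.04 ± 0.188 CPM, IER3 from 102 ± 9.10 to 34.7 ± 3.31 CPM and DUSP5 from 108 ± 6.16 to 56.9 ± 4.85 CPM. AREG, a ligand of the EGF receptor, fell from 20.8 ± 2.40 to 2.75 ± 0.471 CPM. Tubulins and microtubule regulators had 13 of 20 lower and 3 higher (median -0.50, camera adjusted p = 2.23e-07). STMN1 was at -1.36 (SE 0.06), TUBB4B at -1.19 (SE 0.06) and TUBA1B at -1.18 (SE 0.05). Heat shock genes had 10 of 14 lower and 1 higher (median -0.34, camera adjusted p = 4.28e-04, and 0.0457 with an estimated correlation). The chaperone gene HSP90AA1 was at -1.06 (SE 0.06), HSPE1 at -0.95 (SE 0.09) and HSPH1 at -0.78 (SE 0.06).

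Other groups rose in SUM159. SRF/MRTF targets of the cytoskeleton had 12 of 19 higher and 3 lower (median 0.30, camera adjusted p = 3.96e-05, and 0.046 with an estimated correlation). The actin-binding gene TAGLN rose from 9.70 ± 0.507 to 36 ± 5.84 CPM, the myosin light chain MYL9 from 48.4 ± 0.779 to 124 ± 6.91 CPM and the tropomyosin TPM1 from 323 ± 5.69 to 599 ± 16.9 CPM. Autophagy and lysosome genes had 15 of 27 higher and 2 lower (median 0.16, camera adjusted p = 2.17e-05). GPNMB, a lysosomal glycoprotein, rose from 0.657 ± 0.179 to 16.9 ± 1.77 CPM, the protease CTSD from 177 ± 3.61 to 587 ± 60.1 CPM and SQSTM1 from 278 ± 15.4 to 613 ± 41.8 CPM. Aryl hydrocarbon receptor targets had 5 of 7 higher and 2 lower (median 0.48, camera adjusted p = 6.77e-04). The receptor's repressor AHRR rose from 67.5 ± 1.43 to 161 ± 3.14 CPM, with the amino acid transporter SLC7A5 at 1.10 (SE 0.07) and ALDH1A3 at 0.48 (SE 0.11). Further large rises were PAPPA2, a protease of IGF-binding proteins, from 0.936 ± 0.243 to 16.2 ± 1.61 CPM and GDF15 from 1.66 ± 0.357 to 16.9 ± 2.47 CPM. The lipid droplet gene PLIN4 rose from 1.18 ± 0.294 to 10.9 ± 1.03 CPM and PDK4, which inhibits pyruvate dehydrogenase, from 5.69 ± 1.09 to 51 ± 3.22 CPM.

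Calls of 3 lists that rose in SUM159 did not hold with an estimated correlation. Hypoxia and glycolysis genes had 14 (15 adjusted over the list alone) of 24 higher and 6 lower (median 0.41, camera adjusted p = 5.98e-05; adjusted p = 0.0566 with an estimated correlation). PPFIA4 was at 1.66 (SE 0.12), NDRG1 at 1.37 (SE 0.05) and the angiogenic factor VEGFA at 1.27 (SE 0.05). Extracellular matrix and mesenchymal genes had 17 of 34 higher and 6 lower (median 0.23, camera adjusted p = 6.66e-05; adjusted p = 0.113 with an estimated correlation). LOX, a collagen crosslinker, was at 1.42 (SE 0.06) and COL6A1 at 1.27 (SE 0.06), while COL3A1 fell by 1.19. Cytosolic ribosomal proteins had 33 (35 adjusted over the list alone) of 36 higher (median 0.41, camera adjusted p = 1.14e-08; adjusted p = 0.218 with an estimated correlation). RPL37 was at 0.80 (SE 0.12), RPS18 at 0.57 (SE 0.12) and RPL23 at 0.61 (SE 0.18), the last not called in a fit of SUM159 alone (adjusted p = 0.0889) or with the replicate number as a block (0.0751). Reads of these genes can be shared with processed pseudogenes, whose share of counts was 0.505% with DMSO and 0.65% with YES1i (exact p = 0.0286).

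For the other lists in SUM159 there was no camera call. The p53 targets had median -0.08, adjusted p = 0.946, with a mean of 0.02 and a test direction of up. YAP/TAZ targets had median 0.01, adjusted p = 0.83, and IGFBP3, which binds insulin-like growth factors, rose from 3.55 ± 0.316 to 19.5 ± 1.43 CPM. CYR61 had a log2 fold change of 0.09 (edgeR adjusted p = 0.252), called with upper quartile scaling (0.20, adjusted p = 0.00401), and CTGF fell by 0.82. Integrated stress and unfolded protein response genes had median 0.54, adjusted p = 0.0509, and PDIA4, an endoplasmic reticulum foldase, fell from 376 ± 8.17 to 164 ± 11.5 CPM. That list was called with RLE (adjusted p = 0.0347) or upper quartile scaling (0.0222), no filter (0.00811) and a mean count filter (0.0465). It was also called without MDA-MB-231 DMSO replicate 1 (0.0427), 2 (0.0415), 3 (0.0396) or 4 (0.0432) and YES1i replicate 2 (0.0496), 3 (0.0487) or 4 (0.0457). The same held without SUM159 DMSO replicate 2 (0.0016) and YES1i replicate 2 (0.0203) or 4 (0.0468). Drug efflux transporters (median 0.11, adjusted p = 0.152) included ABCC3 at 0.88 (SE 0.05). ABCB1 went from 3.57 ± 0.530 to 2.58 ± 0.707 CPM (edgeR adjusted p = 0.0972), called with limma-voom (adjusted p = 0.0204) or without YES1i replicate 2 (0.0478). Interferon response genes (median 0.05, adjusted p = 0.878) included OAS3 at -1.31 (SE 0.07). Epithelial genes (median 0.15, adjusted p = 0.435, test direction down) included the basal keratin KRT5, which fell from 12.3 ± 2.04 to 3.03 ± 0.257 CPM. Apoptosis regulators (median -0.07, adjusted p = 0.743, with a mean of 0.19 and a test direction of up) included BMF at 2.26 (SE 0.09). CDKN1A fell from 114 ± 4.85 to 92.6 ± 6.77 CPM, and TUBB3 had a log2 fold change of 0.06 (SE 0.30) (edgeR adjusted p = 0.885). Mitochondrially encoded mRNAs (median -0.10, adjusted p = 0.576) included MT-CO3 at -1.11 (SE 0.11). Replication-dependent histones (median -0.15, adjusted p = 0.955) included HIST1H2AC at 1.04 (SE 0.10), and endothelial and fibroblast markers (median 0.64, adjusted p = 0.259) COL3A1. The leukocyte marker CD14 had a log2 fold change of 1.69 (edgeR adjusted p = 1.42e-06) and CSF1R of 0.43 (edgeR adjusted p = 0.442). Values of TUBG1, TAGLN, ACAT2, AHRR, ALDH1A3, LOX, PLIN4, ITGB4 and MT-CO3 are uncertain for the same reason of overlap.

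**Figure D1:**
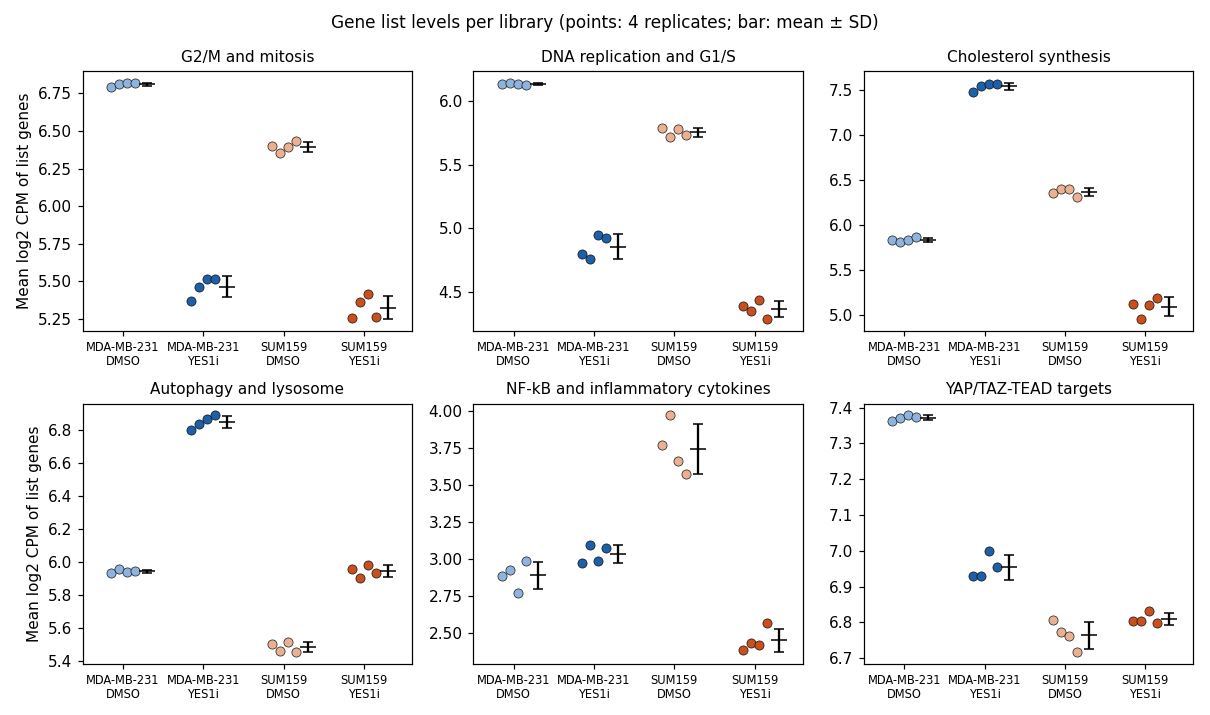
Mean log2 CPM of the tested genes of 6 lists in each of the 16 libraries, with points for the 4 replicates of a group and a bar for their mean ± SD. Cholesterol synthesis is higher with YES1i in MDA-MB-231 and lower in SUM159, with list medians of 1.73 and -1.10, while G2/M and DNA replication are lower with YES1i in both lines.

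The lines differed most in cholesterol synthesis, where all 24 genes had a more positive change in MDA-MB-231, with a median difference of 3.03 on the log2 scale. HMGCS1 differed by 6.15 (SE 0.09), MSMO1 by 4.50 (SE 0.10) and LIPG by 5.39 (SE 0.14). Each was higher with YES1i in MDA-MB-231 and lower in SUM159. ABCA1 went the other way, with a difference of -4.91 (SE 0.13). CXCL8 differed by 5.66 (SE 0.16), and in MDA-MB-231 went from 5.54 ± 0.655 to 5.68 ± 0.596 CPM. In all, the change was more positive in MDA-MB-231 for 3362 genes and more positive in SUM159 for 2127 (edgeR interaction test, adjusted p under 0.05), at least 2-fold apart for 542 and 560. Genes more positive in MDA-MB-231 made up 61.2% of these, but 43.9% with upper quartile scaling (2339 and 2987).

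Of the 28 lists tested, camera called 12 for the difference, of which 6 hold with an estimated correlation. More positive in MDA-MB-231 was cholesterol synthesis (camera adjusted p = 1.18e-302, and 4.55e-08 with an estimated correlation). NF-kB targets and cytokines were too, with 17 (19 adjusted over the list alone) of 23 more positive there (median 1.48). Their camera adjusted p was 1.64e-16, and 0.00784 with an estimated correlation. So were ERK output (median 0.50, camera adjusted p = 6.17e-13) and autophagy and lysosome genes (median 0.53, adjusted p = 8.12e-11). More positive in SUM159 were YAP/TAZ targets (median -0.46, camera adjusted p = 7.11e-09) and SRF/MRTF targets (median -0.37, camera adjusted p = 2.56e-07). For YAP/TAZ targets 15 (18 adjusted over the list alone) of 22 members were more positive in SUM159. The other called lists did not hold. G2/M had a median difference of -0.29 (adjusted p = 0.254 with an estimated correlation) and kinetochore genes of -0.26 (adjusted p = 0.213 with an estimated correlation). Tubulins had 0.23 (adjusted p = 0.212 with an estimated correlation) and hypoxia genes -0.40 (adjusted p = 0.0582 with an estimated correlation). Extracellular matrix genes had -0.33 (adjusted p = 0.185 with an estimated correlation) and ribosomal proteins -0.42 (adjusted p = 0.212 with an estimated correlation). The 16 lists with no call had camera adjusted p from 0.0802 for aryl hydrocarbon receptor targets to 0.93 for apoptosis regulators. Of these, centrosome and DNA repair genes were called with no low-count filter (adjusted p = 0.0457 for each). Among the 16 the median difference of integrated stress genes was 0.16, of histones 0.05 and of endothelial markers 0.03, each with a test direction of down. Heat shock genes (median 0.04), epithelial genes (0.11) and apoptosis regulators (0.08) had a mean below 0 and a test direction of up. The named genes with the most positive differences in SUM159, besides ABCA1, were IGFBP3 at -2.96 (SE 0.11), the acute phase gene SAA1 at -2.45 (SE 0.13) and the cornified envelope gene PPL at -2.35 (SE 0.11). SAA1 went from 37.3 ± 1.58 to 13.6 ± 1.36 CPM in MDA-MB-231 and from 19.2 ± 1.33 to 38.6 ± 5.0 CPM in SUM159. PPL went from 78.4 ± 2.93 to 42.9 ± 3.06 CPM in MDA-MB-231 and from 11.1 ± 1.18 to 30.6 ± 2.35 CPM in SUM159. The lines were grown in different media, so line and medium cannot be separated.

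**Figure D2:**
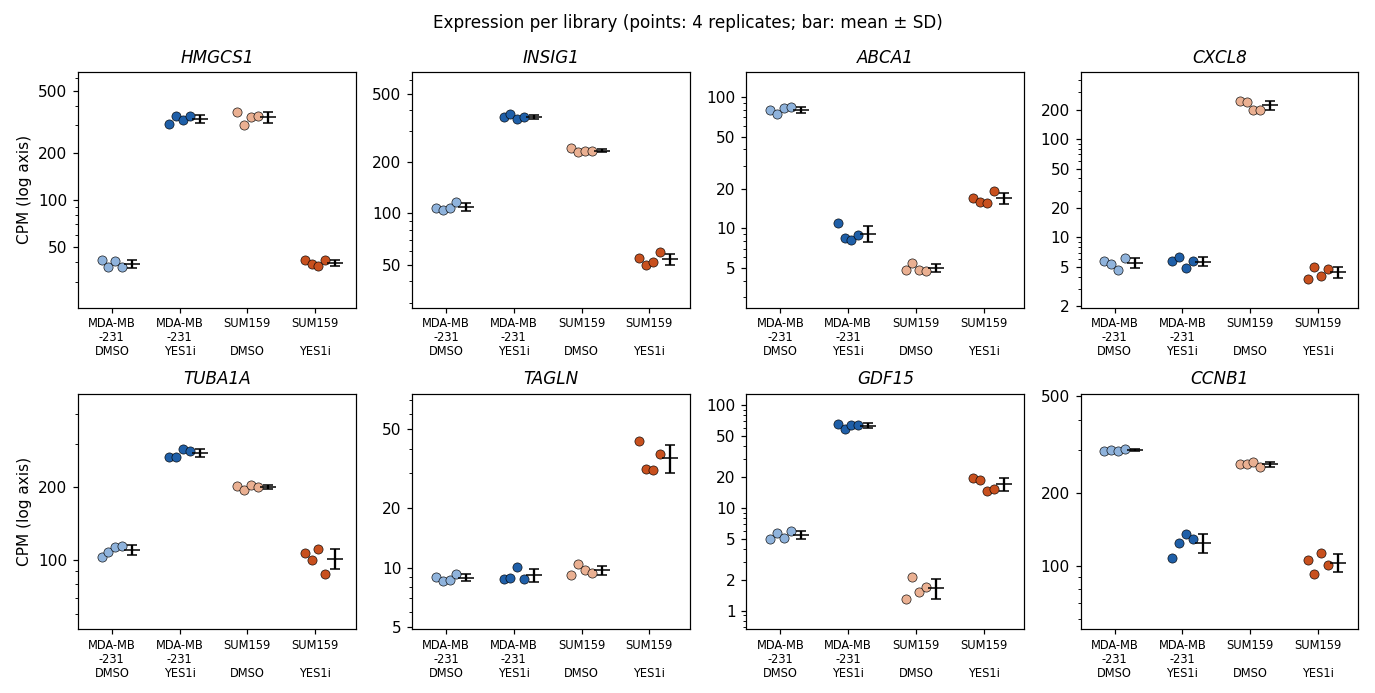
CPM on a log axis of 8 genes in each of the 16 libraries, with points for the 4 replicates of each group of line and treatment. HMGCS1 and INSIG1 move in opposite directions in the lines, CCNB1 is lower with YES1i in both, and CXCL8 has a log2 fold change of -5.64 in SUM159 and 0.03 in MDA-MB-231.

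The responses also overlapped. Among genes of the cell cycle, RRM2 had log2 fold changes of -1.93 in MDA-MB-231 and -1.95 in SUM159, with a difference of 0.02 (SE 0.13) (edgeR adjusted p = 0.965), and AURKA of -1.33 and -1.33. GDF15 rose by 3.53 and 3.41, PDK4 by 3.13 and 3.16, and BMF by 2.57 and 2.26. In all, 2192 genes were higher with YES1i in both lines, where 1189 would be found for independent lists, and 2468 were lower in both, against 1031. Of these, 703 and 714 also differed in size between the lines. Another 595 genes rose in MDA-MB-231 and fell in SUM159 (1255 for independent lists), and 317 the reverse (977). The lines had separate DMSO libraries. With RLE scaling more genes were higher than lower in both lines (2420 and 2364), as with DESeq2 (2473 and 2390) and upper quartile scaling (2834 and 2046). Across the 17647 genes, which are not independent replicates, log2 fold changes had a Pearson correlation of 0.367 and a Spearman correlation of 0.430, and 64.9% had the same sign. The Pearson correlation was 0.103 with no low-count filter.

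**Figure D3:**
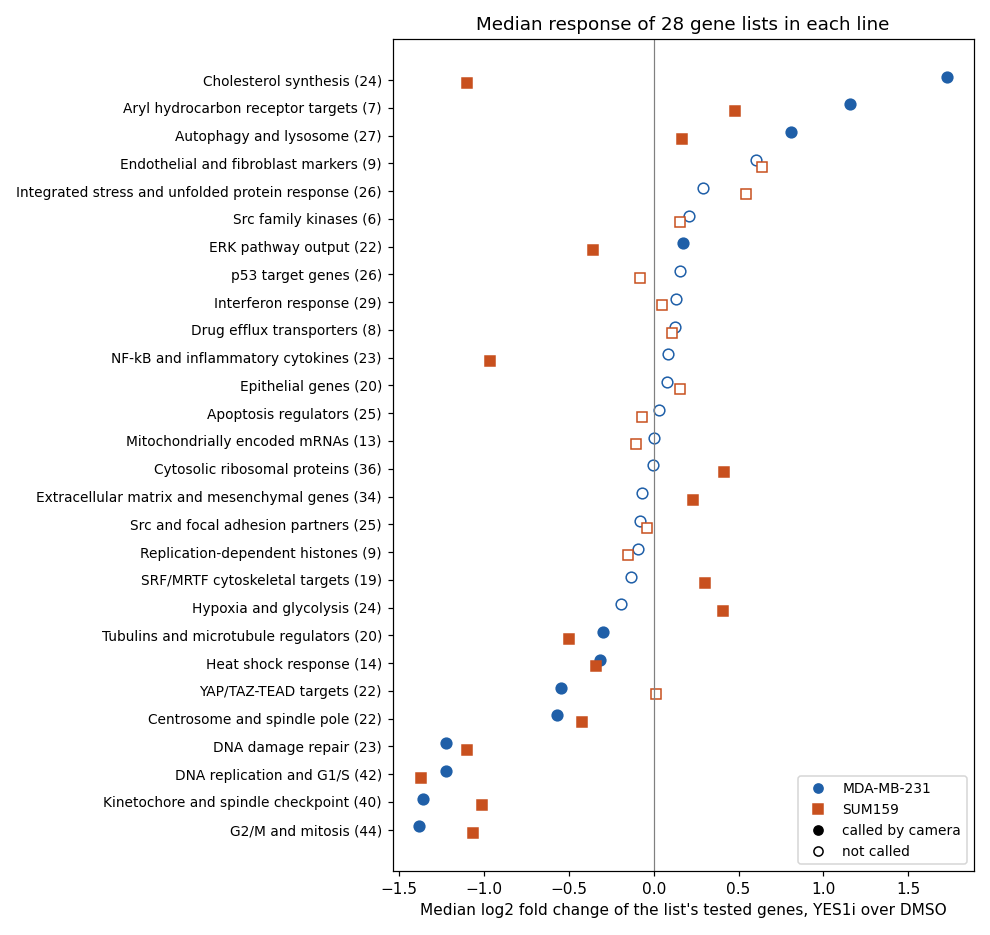
Median log2 fold change (YES1i over DMSO) of each list in MDA-MB-231 and SUM159, with filled points for lists called by camera. Lists of mitosis, replication and repair lie below 0 in both lines, and cholesterol synthesis lies at 1.73 in MDA-MB-231 and -1.10 in SUM159.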

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

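The tests of swapped labels, scaling, library composition, mitochondrial transcripts and carry-over of RNA were chosen only after the result was seen. So were the lists of quiescence and of LXR targets, whose p-values are adjusted over 8 lists chosen in that way. Of 122 named genes, 82 changed by a different amount in the lines in edgeR's interaction test, 45 more positive in MDA-MB-231 and 37 in SUM159. Over all tested genes the share was 31.1%. The named genes were picked in part for large changes or called differences, so a higher share was built in. Values in brackets are the log2 fold change in MDA-MB-231 minus that in SUM159. For sterol and lipid genes they were HMGCS1 (6.15), LIPG (5.39), MSMO1 (4.50), INSIG1 (3.85), TM7SF2 (3.10), ACAT2 (3.05), PLIN4 (-2.02) and ABCA1 (-4.91). For inflammatory and acute phase genes they were CXCL8 (5.66), CXCL2 (2.91), CXCL3 (1.79), IL11 (-1.87) and SAA1 (-2.45). Genes of ERK output and growth factor signalling had AREG (2.85), EGR1 (2.44), IER3 (2.00), DUSP5 (1.96), ETV1 (1.19), SPRY2 (1.07), LYN (0.59), FYN (-0.35) and AXL (-0.69). Lysosomal and stress genes had ATP6V0D2 (4.76), SQSTM1 (1.27), NEU1 (1.22), CTSA (0.97), CTSD (-0.46), GPNMB (-1.24), NUPR1 (1.65), CDKN1A (1.204) and PDIA4 (0.84). Heat shock genes had HSP90AA1 (0.75), HSPH1 (0.42), HSPE1 (0.42) and HSPA4L (-0.42). Tubulins and their partners had TUBA1A (2.31), TUBB4B (0.56), TUBG1 (0.33) and STMN1 (0.26). Cell cycle and repair genes had CENPI (0.60), MYBL2 (0.46), CLSPN (0.45), BUB1 (-0.25), FOXM1 (-0.26), MKI67 (-0.34), RAD51AP1 (-0.35), PLK1 (-0.41), SKA3 (-0.59), CENPK (-0.74) and CEP152 (-0.81). Targets of the aryl hydrocarbon receptor and of hypoxia had CYP1B1 (1.59), CYP1A1 (0.71), TIPARP (1.34), ALDOC (1.503), NDRG1 (-0.40), VEGFA (-0.44), SLC7A5 (-1.70) and PPFIA4 (-1.85). Matrix, adhesion and cytoskeleton genes had FN1 (1.74), PECAM1 (1.32), COL6A1 (-0.27), CAV1 (-0.42), LOX (-0.90), TPM1 (-0.93), ITGB4 (-1.09), MYL9 (-1.49), TAGLN (-1.85) and PPL (-2.35). YAP/TAZ targets had CTGF (-0.22), CYR61 (-0.80) and IGFBP3 (-2.96). The rest were KCP (4.36), C6orf223 (3.91), IFI27 (1.09), OAS3 (0.47), MT-CO3 (1.04), ABCC3 (0.86), RPS18 (-0.48), RPL35 (-0.52), RPL37 (-0.61), ZNF488 (-0.74) and MARCH4 (-1.47). The 12 lists called by camera for the difference had medians of 3.03 for cholesterol synthesis, 1.48 for NF-kB, 0.53 for autophagy and lysosome, 0.50 for ERK output and 0.23 for tubulins. They were -0.46 for YAP/TAZ, -0.42 for ribosomal proteins, -0.40 for hypoxia, -0.37 for SRF, -0.33 for extracellular matrix, -0.29 for G2/M and -0.26 for the kinetochore. Of these 12, 6 lost the call: tubulins, ribosomal proteins and hypoxia had adjusted p = 0.212 with an estimated correlation, adjusted p = 0.212 with an estimated correlation and adjusted p = 0.0582 with an estimated correlation, in that order. Extracellular matrix, G2/M and the kinetochore had adjusted p = 0.185 with an estimated correlation, adjusted p = 0.254 with an estimated correlation and adjusted p = 0.213 with an estimated correlation.

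Of 476 sets of 4 replicates, 28 held a library far from the other 3, where chance gives about 1 in 20. SUM159 YES1i replicate 2 held 8 of these, with mitochondrial rRNA at 1.48% and protein-coding genes at 95.7% of counts. In it the mean log2 CPM of p53 targets was 4.22 and of SRF targets 7.41, and SRC stood at 72.5, DUSP5 at 49.8, HSPE1 at 31.2 and NDRG1 at 349 CPM. SUM159 YES1i replicate 3 held 4, with YAP/TAZ targets at 6.83 and aryl hydrocarbon receptor targets at 5.98 (mean log2 CPM), BLK at 3.54 and TUBB3 at 1.99 CPM. Of SUM159 DMSO libraries, replicate 1 had AURKA at 87.5 and PPL at 9.33 CPM, and replicate 2 ABCA1 at 5.49 and TUBB4B at 593 CPM. Replicate 3 had interferon genes at 2.16 (mean log2 CPM) and replicate 4 CTSD at 171 CPM. Of MDA-MB-231 DMSO libraries, replicate 3 had endothelial and fibroblast markers at -0.26 (mean log2 CPM), PLK4 at 70.0 and NUAK2 at 9.46 CPM. Replicate 2 had AXL at 1386 CPM and replicate 1 TIPARP at 46.9 CPM. With YES1i, MDA-MB-231 replicate 3 had ATP6V0D2 at 11.8 and AXL at 772 CPM, replicate 2 GDF15 at 57.9, replicate 1 MARCH4 at 1.605 and replicate 4 BMF at 36.9 CPM.

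Cholesterol synthesis genes rose in MDA-MB-231 and fell in SUM159. Swapped treatment labels in a line would also reverse the other genes, if the lines otherwise respond alike. Log2 fold changes of the other genes correlated at 0.376 between the lines, which argues against a swap but cannot exclude it. The choice among 4 scalings does not explain the opposite changes of the list. Under each, the list medians had opposite signs and the smaller was at least 6.91 times the largest median of all genes. Counts are relative to each library and most scalings hold that median near 0, so a change in total RNA per cell could not be seen. Of 8 listed genes that LXR induces with sterols, 5 rose and 1 fell in MDA-MB-231 (median 1.01, camera adjusted p = 0.00908; adjusted p = 0.0698 with an estimated correlation) and 6 rose and 1 fell in SUM159 (median 0.66), with a median difference of -0.16 (adjusted p = 0.0984). A fall in sterol level in MDA-MB-231 with a rise in SUM159 may be a cause and cannot be told apart from others, since that test was not called, while ABCA1, which LXR also induces but which is outside the list, fell in MDA-MB-231 and rose in SUM159.

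Mitotic and replication genes fell in both lines. A shift in library composition is excluded, since the lowest median of genes at 5 CPM or more was -0.079 over both lines and 4 scalings. Genes of quiescence and growth arrest rose, 14 of 15 in MDA-MB-231 (median 0.72, camera adjusted p = 1.04e-10) and 10 with 3 lower in SUM159 (median 0.31, adjusted p = 0.00683). Of genes chosen after their values were seen, the growth arrest gene YPEL3 rose by 1.604 and 1.43 and CCNG2 by 0.94 and 0.54. The 3 lower in SUM159 were TOB1 (-0.34), TXNIP (-0.31) and KLF6 (-0.22). The cell cycle inhibitor CDKN1A, outside this list, also fell in SUM159. Fewer cycling cells are a candidate explanation, which cell counts or DNA content would be needed to test further.

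The share of mitochondrial rRNA rose in both lines. A rise of all mitochondrial transcripts is excluded, since the share of mitochondrial mRNA was at most 1.08 times that with DMSO. In MDA-MB-231 the share of 21 listed small RNAs was 0.422 times that with DMSO (0.0578 to 0.785 at 2 SE, exact p = 0.0286), so these RNAs did not rise. They held only 0.0097% of counts with DMSO and 0.0041% with YES1i (SD 0.0035%) there, and may themselves change with treatment. They therefore cannot exclude more carry-over of mitochondrial rRNA. In SUM159 the ratio was 1.07 (0.375 to 1.76, exact p = 0.857), which leaves a rise or a fall open at this spread. More carry-over of RNA without a poly(A) tail may be a cause in either line and cannot be told apart from others.

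Other splits of the libraries were counted as well. For genes changed in MDA-MB-231, the real split called 8629 genes and the others at most 1 (1 of 35 splits as large). In SUM159 the counts were 9105 and 22 (1 of 35), and for the difference between lines 5489 and 2775 (1 of 100). The counts thus follow the treatment labels of these libraries. Every other split of a line mixed the treatments within a group, which widens the spread and lowers the count. The libraries of a group are described as technical replicates, so the splits cannot exclude a chance difference between single cultures. Genes changed the same way in both lines (4660 and 0, 1 of 100) add no separate evidence, since other splits of a line called almost no genes. For lists in MDA-MB-231 the real split called 12 and the others at most 11 (1 of 35). ERK output, among the 12, lost its call under several alternatives (camera adjusted p = 0.0504 with RLE scaling). In SUM159 the numbers of lists were 16 and 17 (6 of 35 as large), and for the difference 12 and 15 (32 of 100). Splits with 3 libraries of a treatment on each side called 8 to 11 lists in MDA-MB-231 and 10 to 17 in SUM159. Such splits keep part of the treatment difference, so these numbers of lists cannot decide on chance. The 18 splits with 2 and 2 called at most 2 lists in MDA-MB-231 and 3 in SUM159.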

How the results depend on the processing

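No test of this part was chosen after its result was seen. No called change of a named gene or list changed sign, while values without a call did, such as TUBB3 in SUM159 (-0.10 to 0.21) and the aryl hydrocarbon receptor difference (-0.09 to 0.82). Balances of called genes turned. In a fit per line MDA-MB-231 had 4503 higher and 4906 lower, while SUM159, at 4026 and 4448, kept its balance. More genes were then called in MDA-MB-231 than in SUM159, the reverse of the shared fit. SUM159 had 5052 and 4137 with RLE, 5105 and 4185 with DESeq2, 4495 and 4458 with no filter and 5985 and 3454 with upper quartile scaling. The last gave 2339 genes more positive in MDA-MB-231 and 2987 in SUM159. Genes higher and lower in both lines were 2420 and 2364 with RLE, 2473 and 2390 with DESeq2 and 2834 and 2046 with upper quartile scaling. The correlation between lines was 0.408 with limma-voom, 0.103 without a filter on low counts and 0.400 with a filter at a mean count of 10, and 0.331 to 0.357 with each library left out (jackknife SE 0.0250). With an adjusted p under 0.01, 1372 genes were more positive in SUM159. With a log2 fold change of at least 1, genes higher and lower were 1114 and 670 in MDA-MB-231, 1186 and 564 in SUM159, and 296 and 260 in both lines, and 542 and 560 for the difference. In the glmTreat test against 1.2-fold they were 2859 and 2124, 2651 and 2633, and 1059 and 1181, and 1736 and 1089 for the difference. With each library left out, genes higher and lower ranged over 4366 to 4980 and 3641 to 4128 in MDA-MB-231, 4030 to 4579 and 4350 to 4625 in SUM159, 2046 to 2242 and 2297 to 2576 in both lines, and 2950 to 3428 and 1932 to 2172 for the difference. The highest MDA-MB-231 counts came without SUM159 YES1i replicate 2, a library of the other line. With the replicate block, genes higher and lower were 4426 and 3623 in MDA-MB-231, 4071 and 4345 in SUM159, and 2873 and 1768 for the difference. Libraries with one replicate number correlated at -0.107 to 0.0116, none best with its own number, so the numbers were not used as pairs. Under the block RPL23 in SUM159 (adjusted p = 0.0751) and ERK output in MDA-MB-231 (adjusted p = 0.0573) lost their calls. Outside left-out libraries, 3 results of single genes lost a call under some alternative and 4 gained one, and 12 of lists lost and 43 gained one, mostly with fry, which does not compare a list with other genes. The cause was not tested, except that stricter limits call fewer genes by construction. At this depth and number of libraries, simulated 1.5-fold differences between lines were found for 73.3% of genes. Those genes all had 5 CPM or more in each line, and far fewer genes changed than in the data, so this share may not hold for all tested genes.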

Other observations

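The lists of this part were chosen after the data were seen, and tested with camera, adjusted over the 8 of them with enough tested genes. Fatty acid synthesis genes followed those of sterols: 11 of 14 rose and 1 fell in MDA-MB-231 (median 0.62, camera adjusted p = 3.5e-13), and 11 fell in SUM159 (median -0.59, adjusted p = 3.19e-07). The difference had a camera adjusted p = 6.61e-42, and 2.14e-06 with an estimated correlation. The fatty acid synthase FASN had log2 fold changes of 1.37 and -1.08, the desaturase SCD of 1.84 and -0.94 and the acetyl-CoA synthetase ACSS2 of 2.26 and -0.74. Genes of PPAR and fatty acid oxidation rose in MDA-MB-231, 12 of 17 (median 0.42, camera adjusted p = 6.11e-07), and in SUM159, 9 with 2 lower (median 0.19, camera adjusted p = 0.0101; adjusted p = 0.215 with an estimated correlation). PLIN2, a coat protein of lipid droplets, had log2 fold changes of 1.71 and 2.83, and CPT1A, which brings fatty acids into mitochondria, of 1.00 and 0.61.

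Subunits of the V-ATPase, the proton pump of lysosomes, rose in MDA-MB-231 (12 of 13, median 0.45, camera adjusted p = 5.99e-05), with a median of 0.03 in SUM159 (adjusted p = 0.48) and a test of the difference at an adjusted p = 3.48e-04. Ribosome biogenesis genes fell in both lines, 23 of 24 in MDA-MB-231 (median -0.48, camera adjusted p = 8.15e-09) and 23 in SUM159 (median -0.45, adjusted p = 3.19e-07). Aminoacyl-tRNA synthetases had 4 higher and 8 lower of 18 in MDA-MB-231 (camera adjusted p = 0.153), and 12 and 3 in SUM159 (adjusted p = 0.0137; adjusted p = 0.279 with an estimated correlation). Nuclear-encoded genes of the respiratory chain had 10 of 24 lower in MDA-MB-231 (camera adjusted p = 0.17) and 15 in SUM159 (median -0.33, adjusted p = 0.00683; adjusted p = 0.348 with an estimated correlation).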
